A study of Mus musculus with 2 samples.

How the data were processed

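Nuclei of the ascending aorta and arch of Wnt1-Cre; Rosa26-mTmG mice were sequenced with a droplet method, tissue being pooled by sex into 1 Female and 1 Male library. Per the labels, each pool was split into technical replicates; the barcodes do not show the splits, so no value per split was computed. The deposited values are raw UMI counts per gene and barcode, with no normalization by the authors recorded. Per the submitters' processing notes, GRCm38, STAR, Cell Ranger and Seurat 4.4.0 were used, and per the file headers the matrices came from Cell Ranger 7.0.0. The annotation version, the strand setting and the use of intronic reads are not given in the sources used here. The matrices hold 54754 features, among them tdTomato and GFP, and every deposited barcode has at least 500 UMIs. Positions came from a GRCm38 gene annotation matched by Ensembl identifier, which placed 54723 features.

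Genes that overlap another model are uncertain where strand was not used in counting. Of 112 genes named in the sex comparison, 68 overlap another model and 13 a protein-coding one, including Mpp6 (Gsdme), Acss2 (Ggt7 and Gss), Pgm3 (Dop1a), Nnat (Blcap), Angpt2 (Mcph1) and Prg4 (Tpr). Of 44 genes named in the reporter comparison, 37 overlap another model and 6 a protein-coding one: Mfap4 (Mapk7), Cacna1d (Chdh and Dcp1a), Kcnip4 (5730480H06Rik), Art3 (Cxcl10), Dlx6os1 (Dlx6) and Gt(ROSA)26Sor (Thumpd3), the last 2 annotated as antisense. C4b has a near-identical copy, C4a, and its counts are uncertain for that reason.

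Nuclei with at least 300 genes and at most 10% mitochondrial UMIs were kept, 18859 of 18872 Female and 20645 of 20659 Male barcodes. Doublets were called per library with scrublet at an expected rate of 0.08, and the 948 Female (5.03%) and 1556 Male (7.54%) nuclei called were removed. The median mitochondrial share of retained nuclei was 0.172% and 0.191%. A total of 4287 barcode sequences occurred in both libraries. Both libraries were clustered together in scanpy 1.11.5 on 2000 variable genes, 30 principal components and 15 neighbours with Leiden resolution 0.8 (igraph 0.11.9), leaving out sex-linked, mitochondrial, ribosomal protein and haemoglobin genes, which gave 24 clusters. A cluster was named as a class from markers fixed before the data were examined, by the class whose markers scored highest, with at least 3 markers found in 10% or more of its nuclei. The score was set after the clusters were seen. Classes with at least 300 nuclei in each library were compared. Smooth muscle-like nuclei did not pass the check that no cluster has more leading markers of another class than of its own, and were compared by cluster number, which gave 9 units. Smooth muscle-like nuclei were also clustered alone at resolution 0.4. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0 were used.

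For the sexes, UMIs were summed per library and unit and scaled to CPM, and the log2 ratio of Female to Male CPM was taken after adding 5 CPM to each. Genes with at least 50 UMIs over both libraries and 20 CPM in either were kept. Genes at least 2-fold apart were counted by size alone, since 1 library per sex allows no test. Shares carry exact Clopper-Pearson intervals and counts exact Poisson intervals, all at 95% and covering counting error only. The rule for named genes, fixed beforehand, took up to 12 genes each way in fibroblast and smooth muscle units and up to 5 in others, leaving out gene models without a proper symbol and genes under 0.1 of the CPM of their highest class in both libraries, which free RNA can give. Those left out as possible free RNA numbered 3 in endothelial, 6 in fibroblast, 9 in smooth muscle cluster 1, 8 in brown adipocyte, 7 in smooth muscle cluster 3, 10 in macrophage and 19 in white adipocyte units, and 0 in smooth muscle clusters 0 and 2. Genes apart the same way in every unit where they passed, in 3 units or more, were named once, and up to 4 members were named per gene list. Some genes that the rule takes are not reported here. The members of 30 gene lists were fixed beforehand; a list's median was placed among 10000 random lists of the same size matched on expression, where at least 4 members passed. Intervals of list medians and of the gaps between clock arms came from 500 Poisson draws of the summed UMIs. Of 190 pairs of list and unit, 74 lay outside the middle 95% of random lists. The pairs described were picked after their medians and alternatives had been seen, and nothing is stated on the others.

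The reporter was summarised as GFP and tdTomato UMIs per unit and library. Nuclei with GFP UMIs alone were compared with nuclei with tdTomato UMIs alone in smooth muscle clusters 0 and 2 and fibroblast clusters 9 and 13. UMIs were summed per library and reporter, and the 4 sums were tested with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, library as a block, genes with at least 50 UMIs) in R 4.3.3 at a Benjamini-Hochberg adjusted p of 0.05. The SE printed is the absolute log2 fold change over the square root of edgeR's F statistic, and not an error estimated over replicates. DESeq2 1.42.0 was run on the same sums. The comparison, its clusters, its alternatives and the choice of genes called by both tools were made after the data were seen. Nuclei numbered 1085 GFP-only and 944 tdTomato-only in Female and 541 and 414 in Male cluster 0, and 756 and 525, and 955 and 654 in cluster 2. In fibroblast cluster 9 they numbered 228 and 118, and 265 and 130, and in cluster 13 182 and 123, and 155 and 96. The animals in a pool cannot be separated, so p-values do not measure the spread between animals. They rest on how far the difference between the reporters varied between 2 pooled libraries, with dispersion shared across genes.

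The steps were tested on simulated counts. For the sexes, 3-fold changes were recovered for 97% of changed genes in endothelial, 99% in smooth muscle cluster 0 and 98% in cluster 2, 94% in cluster 1, 93% in cluster 3, 97% in fibroblast, 96% in brown and white adipocyte and 89% in macrophage units. Of unchanged genes, 7 of 7034 came out 2-fold apart in smooth muscle cluster 1, 3 of 7172 in macrophages and 0 in the other units. Both libraries were drawn here from 1 profile with counting error alone. Spread between animals or pools, UMIs clumped in few nuclei and clustering were left out, so these numbers are no rate of false 2-fold genes in the data. For the reporter, 2-fold changes were recovered for 58% and 66% of changed genes in smooth muscle clusters 0 and 2 and 39% and 29% in fibroblast clusters 9 and 13, and 4-fold changes for 95%, 94%, 95% and 84%, at a simulated dispersion of 0.02. Unchanged genes called there numbered 9 of 11539, 13 of 11655, 5 of 7874 and 0 of 6171.

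Alternatives fixed before the data were examined were a stricter nuclei filter (500 genes, 5% mitochondrial), doublets kept, Leiden resolution 0.4, variable genes without those 2-fold apart between libraries, separate clustering, TMM scaling, equal weight per nucleus, thinning to 1000 UMIs, pseudocounts of 1 and 20 CPM, no CPM filter, a stricter gene filter (200 UMIs, 50 CPM), and sub-clustering at resolution 0.2 or on thinned nuclei. Those added after the data were seen were the largest cluster of each class alone, smooth muscle cluster 3 without nuclei with a Myh6 UMI, the same clustering alternatives for GFP shares, and those of the reporter comparison: DESeq2, RLE scaling, no library block, minimums of 10 and 200 UMIs, at least 2 reporter UMIs per nucleus, and thinning. Thinning left out nuclei under 1000 UMIs: 248 of 615 Female and 689 of 1488 Male nuclei of smooth muscle cluster 1, 59 of 555 and 97 of 765 of macrophages, and smaller shares of the other units.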

Results

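Nuclei of the mouse ascending aorta and aortic arch were profiled by droplet single-nucleus RNA sequencing. The animals carried Wnt1-Cre, which is active in the embryonic neural crest, and the Rosa26-mTmG reporter, which gives tdTomato in cells without Cre and GFP in Cre-expressing cells and their descendants. Tissue was pooled by sex, giving 1 Female and 1 Male library, each a pool of several animals. The Female library held 79294181 unique molecular identifiers (UMIs) at 18872 barcodes and the Male library 77989549 UMIs at 20659 barcodes. After quality and doublet filters, 17911 Female nuclei with a median of 3464 UMIs and 1685 genes and 19089 Male nuclei with a median of 3011 UMIs and 1532 genes were kept. With 1 library per sex, no test of sex was possible and no value had a replicate check. All intervals of that comparison are 95% intervals that cover counting error only, and differences are stated as between these libraries. Gene positions are spans on GRCm38, and UMIs were counted per whole gene, so exon and intron cannot be told apart.

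The sex-linked genes matched the labels of both libraries. Xist, the RNA that coats the inactive X chromosome, had 85762 UMIs in the Female library and 81 in the Male library. The Y genes were found in the Male library, with 11881 UMIs of Uty, 6260 of Ddx3y, 5523 of Eif2s3y and 3165 of Kdm5d, against 6, 8, 2 and 3 UMIs in the Female library. Usp9y was sparse but lower in the Female library, with 15 against 36 UMIs (ratio scaled to library total 0.41, interval 0.21 to 0.77). Zfy1 (4 Female and 1 Male UMIs) and Zfy2 (4 and 5) were too sparse to separate the libraries. Tsix, transcribed antisense to Xist, had 379 and 41 UMIs, and its reads may include those of Xist where strand was not used in counting. Among X genes reported to escape inactivation, the ratio of Female to Male CPM (UMIs scaled to library total) was 1.70 (1.65 to 1.74) for Kdm6a, 1.54 (1.495 to 1.590) for Kdm5c, 1.51 (1.42 to 1.62) for Eif2s3x, 1.46 (1.37 to 1.57) for Pbdc1, 1.34 (1.30 to 1.39) for Ddx3x and 1.15 (1.13 to 1.17) for Mid1.

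Smooth muscle-like, endothelial-like and fibroblast-like nuclei made up most of both libraries. Smooth muscle-like nuclei formed 42.4% of the Female library (41.7 to 43.1) and 37.2% of the Male library (36.5 to 37.9), and vascular endothelial-like nuclei 27.0% (26.3 to 27.6) and 31.8% (31.1 to 32.5). Fibroblast-like nuclei took 15.3% and 14.9%, a difference of 0.335 percentage points whose interval (-0.395 to 1.07) included no difference. Brown adipocyte-like nuclei, led by Ucp1, Cidea and Ppara, were more frequent in the Female library, with 5.20% (4.88 to 5.54) against 3.05% (2.81 to 3.31). White adipocyte-like nuclei, led by Cyp2e1, Retn and Cfd, differed little, with 3.28% (3.03 to 3.55) and 3.70% (3.44 to 3.98). Macrophage-like nuclei were less frequent in the Female library (3.10% against 4.01%), as were mesothelial-like (1.66% against 2.64%), T or NK-like (0.631% against 1.29%) and lymphatic endothelial-like nuclei (0.357% against 0.623%). B or plasma-like nuclei were more frequent there (0.731% against 0.335%). The remaining classes were small: 28 Female and 19 Male pericyte-like, 25 and 16 Schwann or glial-like, 6 and 34 neutrophil-like, and 12 and 16 epithelial-like nuclei.

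Within the classes, endothelial cluster 6, led by Ankrd33b, Chn2 and Fgfr3, held 7.28% of Female and 11.3% of Male nuclei. Endothelial cluster 5, led by Nrg1 and Thbs1, held 1166 Female nuclei (6.15% to 6.88% of the library) and 1336 Male nuclei (6.64% to 7.37%). Cluster 7, led by Chrm3 and Cyp4b1, differed by -0.391 points (-1.08 to 0.299). Fibroblast cluster 9, led by C7, Plcxd3 and Scara5, held 6.77% of Female and 7.87% of Male nuclei, and fibroblast cluster 13, led by Pex5l, Adamtsl2 and Lsamp, 5.76% and 4.44%. The small fibroblast cluster 4, led by Nlgn1, Chrm2 and Tfap2b, had 97 and 78 nuclei. How tissue was dissected and how nuclei were recovered can set such shares, and neither was measured.

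**Figure D1:**
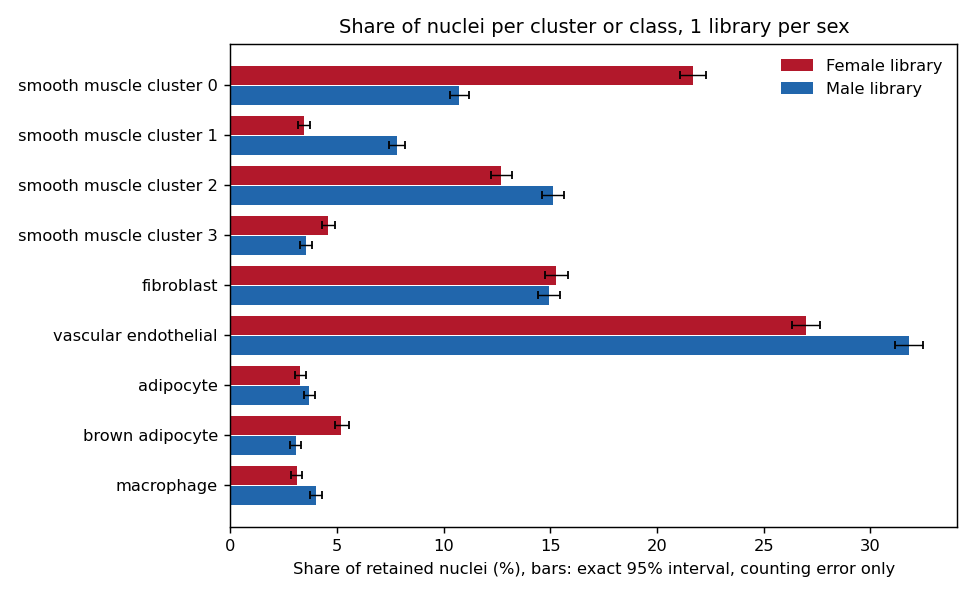
Share of retained nuclei (percent) in the 9 units compared, the 4 smooth muscle clusters and 5 classes (adipocyte stands for white adipocyte), for the Female and the Male library, with exact 95% intervals for counting error. Smooth muscle cluster 0 held 21.7% of Female and 10.7% of Male nuclei.

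The smooth muscle-like nuclei fell into 4 clusters, which were compared by number because a gene of another class led 2 of them. Cluster 0 (leading genes Pdzrn4, Sphkap, Unc5c) held 21.7% of Female and 10.7% of Male nuclei, cluster 2 (Ptprz1, Actn2) 12.7% and 15.1%, cluster 1 (Flna, Myom1, Tagln) 3.43% and 7.80%, and cluster 3 (Lrrtm3, Lrrc7, Adamtsl1) 4.59% and 3.53%. Cluster 1 had shallow nuclei, with a median of 1174 Female and 1050 Male UMIs. When smooth muscle-like nuclei were clustered alone, sub-cluster 1, led by Pcsk5 and Dock10, held 62.3% of Female and 45.4% of Male nuclei, and sub-cluster 0 held 26.5% and 44.5%. Sub-cluster 0 had a median of 1714 UMIs against 4614 in sub-cluster 1, and it was led by Mir6236, Gm26561 and Gm42418. No sub-cluster had a fixed smooth muscle marker among its leading genes, which were ranked against the other smooth muscle-like nuclei. Sub-cluster 2, led by Adamtsl1 and Mdga2, held 835 Female and 690 Male nuclei, and 94.1% of it came from cluster 3. Sub-cluster 3 had 16 Female and 26 Male nuclei. The shares depended on the clustering. With the libraries clustered separately the difference was 2.04 points in place of 10.95 for cluster 0 and -0.697 in place of -4.36 for cluster 1. Cluster 2 was 2.44 points lower in the Female library but 3.05 points higher with the libraries clustered separately. At the lower resolution and with doublets kept, clusters 0 and 2 merged and were together 8.005 and 12.89 points higher in the Female library, and at the lower sub-clustering resolution sub-clusters 0 and 1 merged, at -1.12 points in place of 17.0 for sub-cluster 1, so these values say nothing of cluster 2 or sub-cluster 1 alone.

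Between the sexes, smooth muscle clusters 0 and 2 differed in few genes. Among genes that passed the filter, 3 were at least 2-fold higher in the Female library and 9 in the Male library in cluster 0, and 5 and 9 in cluster 2. In cluster 2 the genes higher in the Female library included Col8a1, a short-chain collagen of vascular matrix (chromosome 16: 57624258 to 57754737; 69.6 against 17.8 CPM, log2 ratio 1.71), Mamdc2 (1.34) and the proprotein convertase Pcsk5 (1.06), which also leads sub-cluster 1. In cluster 0 Gria1, a glutamate receptor subunit, had a log2 ratio of 1.04. Lower in the Female library in both clusters were the zinc finger gene Zbtb16 (chromosome 9: 48654297 to 48836222; -1.64 and -1.53) and Mpp6 (-1.20 and -1.19). Cluster 0 added Tmem82 (-1.38), Vstm4 (-1.13), Capn13 (-1.05) and Papss2 (-1.03), and cluster 2 Vwa3a (-1.21), Myoz2 (-1.21) and Trp53inp1 (-1.08). Ano4, a transmembrane protein of the anoctamin family (chromosome 10: 88948994 to 89344762), was higher in the Female library in smooth muscle clusters 0 (1.68), 2 (1.63) and 3 (273.3 against 19.6 CPM) and in fibroblasts (3.18), the 4 units in which it passed the filter. The split of the counts turned with the clustering: with the libraries clustered separately, cluster 0 had 18 Female-higher and 7 Male-higher genes and cluster 2 had 15 and 19, and on thinned nuclei cluster 0 had 9 and 15 and cluster 2 had 14 and 12. With a pseudocount of 1 CPM 19 and 23 genes were apart in clusters 0 and 2, with 20 CPM 5 in each, and with the stricter gene filter 6 in cluster 0.

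By gene list, contractile genes were slightly lower in the Female library in cluster 2. The median log2 ratio over the 15 measured members was -0.23, below 0 in 12 of them, at percentile 0.11 of random lists matched on expression; Myocd, a coactivator of the contractile programme, was at -0.52, Des at -0.64, Acta2 at -0.23 and Myh11 at -0.09. In cluster 3 the contractile median was -0.17, with 12 of 15 members below 0, while it was -0.05 in both cluster 0 (percentile 17.6) and cluster 1 (percentile 27.1). The 6 measured Notch genes of cluster 2 were all above 0 (median 0.28, percentile 99.9), led by the ligand Jag1 at 0.72 with Notch3 at 0.32. TGF-beta genes had a median of -0.16 there (percentile 0.06, 12 of 18 below 0): Ctgf was at -0.82, while Smad3 was at 0.45. Sex steroid receptors and targets had a median of 0.27 in cluster 2 (percentile 99.0, 4 of 4 above 0), 0.33 in cluster 3, where Nrip1 was at 0.44, and 0.23 in cluster 0 (3 of 4 above 0), but 0.04 in cluster 1 (percentile 60.1, 2 above and 2 below 0). Elastic fibre and fibrillar collagen genes went both ways, with medians of 0.03 in cluster 2 and 0.06 in cluster 0. In cluster 2 Eln was at -0.36 and Mfap4 at -0.69 beside Col8a1, and in cluster 0 Eln was at -0.18 and Col3a1 at 0.61. Genes of heritable thoracic aortic disease had a median of -0.01 in cluster 2, 8 above and 8 below 0, with Tgfbr1 at -0.42. In the same cluster heat shock genes had a median of -0.35 (6 of 6 below 0), immediate early genes of -0.21 (8 of 8 below 0) and ribosomal protein genes of -0.11 (20 of 21 below 0). Of the cluster 2 medians, the contractile was -0.14 and the sex steroid 0.44 on thinned nuclei, the Notch 0.090 and the sex steroid 0.086 with no CPM filter, the TGF-beta -0.10 with the libraries clustered separately and the aortic disease 0.022 without 2-fold genes in the clustering. With doublets kept, which merged clusters 0 and 2, the merged cluster had medians of -0.083 for contractile, -0.077 for TGF-beta and 0.18 for Notch genes.

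Smooth muscle clusters 1 and 3 had fewer UMIs and more genes 2-fold apart, 34 higher in the Female and 58 in the Male library in cluster 1, and 34 and 26 in cluster 3. In cluster 1, Mamdc2 (67 against 28 UMIs), Stk32b (log2 ratio 1.67) and Kcns3 (1.36) were higher in the Female library; Zbtb16 (-1.75) and Tmem82 (-2.18) were lower, and Ttn had 2 against 123 UMIs. In cluster 3, Celf4 (-1.98), Ntm (-1.94), the angiotensin-converting enzyme Ace (40.5 against 118.3 CPM, -1.44) and Zbtb16 (-1.32) were lower in the Female library, and Cntn6 (1.81) and Scube1 (1.46) higher. The top Female genes of cluster 3 were heart muscle genes: all 454 UMIs of Myh6, 383 of 391 of Ttn and 164 of 164 of Kcnj3 lay in 5 of the 822 Female nuclei, and the Male nuclei held 0 UMIs of Myh6. The counts depended on the gene filters, with 298 genes in cluster 1 and 102 in cluster 3 when no CPM minimum was set and 13 and 25 with a stricter gene filter. That of cluster 1, 92 in all, also depended on the nuclei and their clustering, with 16 without 2-fold genes in the clustering, 22 with doublets kept, 37 with the stricter nuclei filter and 42 with the libraries clustered separately. Their split turned too, to 166 Female-higher and 132 Male-higher in cluster 1 with no CPM minimum, and in cluster 3 to 28 and 29 with the stricter nuclei filter and 23 and 28 on thinned nuclei.

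In fibroblast-like nuclei, 22 genes were at least 2-fold higher in the Female library and 35 in the Male library. With a pseudocount of 20 CPM these were 5 and 19, and with the stricter gene filter 15 and 21. Il4ra, a receptor subunit for interleukins, was higher in the Female library (67.8 against 16.5 CPM, log2 ratio 1.76), with Adamts17 (1.49), Ntm (1.29), Mtus2 (1.25), Ldb2 (1.16), Epha4 (1.15), Angpt2 (1.12) and Lsamp (683.5 against 314.7 CPM, 1.11). Lower there were Zbtb16 (437.2 against 1630.5 CPM, -1.89), the complement genes C7 (521.9 against 1778.2 CPM, -1.76) and C4b (-1.49), the metallothioneins Mt2 (-1.66) and Mt1 (-1.28), the proteoglycan Prg4 (-1.52), Shisa9 (-1.83) and Tll2 (12 against 239 UMIs, -2.24). C7 and Lsamp also lead fibroblast clusters 9 and 13, whose shares differed, but by less than these genes did. The ratio of Female to Male shares was 0.861 for cluster 9 and 1.30 for cluster 13. Among 12 measured clock genes, Arntl (-1.21) and Npas2 (-1.30), a paralogue of Clock that can pair with Arntl in its place, were lower in the Female library, while Tef (0.62) and Per3 (0.71) were higher; the list median was 0.28, with 7 above and 5 below 0, and it was 0.47 with no CPM filter and 0.42 with the stricter gene filter. Immediate early genes were slightly lower (median -0.32, 8 of 9 below 0, percentile 0.01; -0.21 in the largest cluster alone), with Nr4a1 at -0.65 and Dusp1 at -0.47. Beside these, markers of other classes lay apart in fibroblasts, contractile genes at a median of 0.20 (8 of 10 above 0) and endothelial function genes at -0.28 (8 of 9 below 0), and 18 of 21 ribosomal protein genes were below 0.

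In endothelial-like nuclei, the most abundant non-muscle class, 1 gene was at least 2-fold higher in the Female library and 19 in the Male library. The first was Kif5c, a kinesin heavy chain (27.1 against 5.27 CPM, log2 ratio 1.64). Lower in the Female library were Cmah, which hydroxylates sialic acid (chromosome 13: 24327404 to 24477377; 8.27 against 96.4 CPM, -2.93), Lrg1 (2.51 against 26.4 CPM, -2.06), Kif26b (-1.69) and Nckap5 (-1.49). Nckap5 was 0.34 in the largest endothelial cluster taken alone, the only one of these genes to reverse there. By list, 10 of 14 endothelial function genes were below 0 (median -0.16, percentile 0.04), with Pecam1 at -0.24 and Thbd at -0.31. All 7 matrix proteases and inhibitors were below 0 (median -0.24), with the inhibitor Timp3 at -0.59 and Mmp14 at -0.57. All 9 mitochondrially encoded genes were below 0 (median -0.40, or -0.25 with no CPM filter), mt-Nd1 at -0.53 among them; such transcripts in nuclei come from outside the nucleus. Ribosomal protein genes were lower by about as much as the endothelial list (median -0.16, 23 of 24 below 0), and contractile genes of smooth muscle were higher (median 0.19, 8 of 9 above 0). In place of 20 genes, 8 were apart with a pseudocount of 20 CPM and with the stricter gene filter, and 13 in the largest cluster alone.

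White adipocyte-like nuclei had the most genes apart among the 9 units, 150 at least 2-fold higher in the Female and 79 in the Male library, although with no CPM filter their 279 were fewer than the 298 of smooth muscle cluster 1. Brown adipocytes had 49 and 31. With a pseudocount of 20 CPM 108 genes were apart in white and 32 in brown adipocytes, and 49 in brown with the stricter gene filter. Immediate early genes, which respond to stimulation within minutes, were higher in the Female library in both. In white adipocytes all 8 measured members were above 0 (median 1.48) and 7 were at least 2-fold higher, with Egr1 at 151.5 against 4.85 CPM (log2 ratio 3.99), Fos at 41.3 against 1.27 CPM (2.88) and Nr4a1 at 1.59. In brown adipocytes all 5 were above 0 (median 1.03) and 3 at least 2-fold higher, with Egr1 at 356 against 4 UMIs and Nr4a1 at 2.71. The white adipocyte median was 0.92 with a pseudocount of 20 CPM and 0.95 with no CPM filter, and the brown adipocyte median 0.66 with no CPM filter. Elovl6, a fatty acid elongase, was higher in Female white adipocytes (5166 against 878.8 CPM, 2.55), as was Pgm3 (2.71). In brown adipocytes Prune2 (2.32), Pgm3 (2.09) and Acss2, a cytosolic acetyl-CoA synthetase (1513 against 452.5 CPM, 1.73), were higher. Lower in the Female library were the glucose transporter Slc2a3 (-2.57), Nnat (-2.51), C4b (-2.38) and the natriuretic peptide receptor Npr3 (-2.35) in white adipocytes, and Zbtb16 (-2.71), the cytochrome P450 gene Cyp2b10 (-2.54), Car5b (-1.73), Tsku (-1.48) and Bmper (-1.41) in brown adipocytes. Nuclear-encoded oxidative phosphorylation genes were slightly higher in Female white adipocytes, 16 of 18 above 0 (median 0.21), with Cox5a at 0.62. Lists of other cell types were higher there by about as much, thermogenic genes of brown adipocytes at a median of 0.19 (percentile 96.2) and contractile genes at 0.22 (percentile 99.3), and brown adipocyte-like nuclei were more frequent in the Female library. In brown adipocytes all 21 measured ribosomal protein genes were below 0 (median -0.23).

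In macrophage-like nuclei, 55 genes were at least 2-fold higher in the Female and 25 in the Male library. The scavenger receptor gene Marco had 57 Female and 0 Male UMIs, and the acute-phase gene Saa3 was at 156.2 against 15.9 CPM (log2 ratio 2.95). The chemokine gene Ccl8 (-1.69), Slc16a14 (-1.78), Ston1 (-1.66), Mpi (-1.64) and Hif3a (-1.55) were lower in the Female library. All 9 measured mitochondrially encoded genes (median 0.58) and 20 of 24 ribosomal protein genes (median 0.34) were above 0, opposite to the endothelial class. The mitochondrially encoded median was 0.29 when each nucleus weighed the same and 0.32 in the largest cluster alone. Rp1 (2.35), Cxcl13 (2.15) and Tgfb2 (2.10) were higher over the whole class but at -0.40, -1.13 and -1.76 in its largest cluster alone. Neither the direction nor the size of the counts was stable, with 50 Female-higher and 57 Male-higher genes when each nucleus weighed the same, and with 29 genes in place of 80 under the stricter gene filter, 36 with a pseudocount of 20 CPM, 48 on thinned nuclei, 145 with a pseudocount of 1 CPM and 191 with no CPM filter.

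Genes that respond to glucocorticoids were lower in the Female library in all 9 units compared. Fkbp5, which encodes a co-chaperone of the glucocorticoid receptor (chromosome 17: 28399094 to 28517527, minus strand), was at least 2-fold lower in each, with a median log2 ratio of -1.89 and a range from -2.69 in brown adipocytes (27.1 against 201.7 CPM) to -1.49 in fibroblasts (248.8 against 706.5 CPM). The list median was -1.22 in fibroblasts, -1.15 in smooth muscle cluster 3, -0.82 in cluster 2, -0.77 in cluster 1, -0.73 in brown adipocytes, -0.69 in smooth muscle cluster 0, -0.62 in white adipocytes, -0.43 in macrophages and -0.36 in endothelial nuclei, each at percentile 0.02 or lower among matched random lists. The sizes and the order of the units depended on the processing: the endothelial median was -0.88 with the stricter gene filter and from -0.63 to -0.62 with no CPM filter, equal weight per nucleus or thinned nuclei, and with no CPM filter it was -0.441 and -0.443 in smooth muscle clusters 0 and 2, -0.75 in cluster 3 and -0.38 in white adipocytes. On thinned nuclei that of macrophages was -0.25, at percentile 3.02. Members below 0 numbered 7 of 8 in fibroblasts, 8 of 9 in brown adipocytes, 7 of 9 in macrophages and 6 of 7 in endothelial nuclei. The random lists drew their genes singly, and 74 of all 190 pairs of list and unit lay outside their middle 95%. Extreme percentiles were therefore not rare in these data, and a percentile is no error rate. Zbtb16 was at -1.25 in endothelial nuclei and -2.11 in white adipocytes. Nr3c1, the gene of the receptor itself, went the other way in all 9 units, from 0.16 in endothelial nuclei to 0.59 in brown adipocytes. Angptl4, a lipoprotein lipase inhibitor, was at least 2-fold lower in the 3 units in which it passed the filter, and the long non-coding Gm12840 in 4. AC154912.3 lies inside Fkbp5 on the same strand, so its values (median -1.72) cannot be told from those of Fkbp5.

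**Figure D2:**
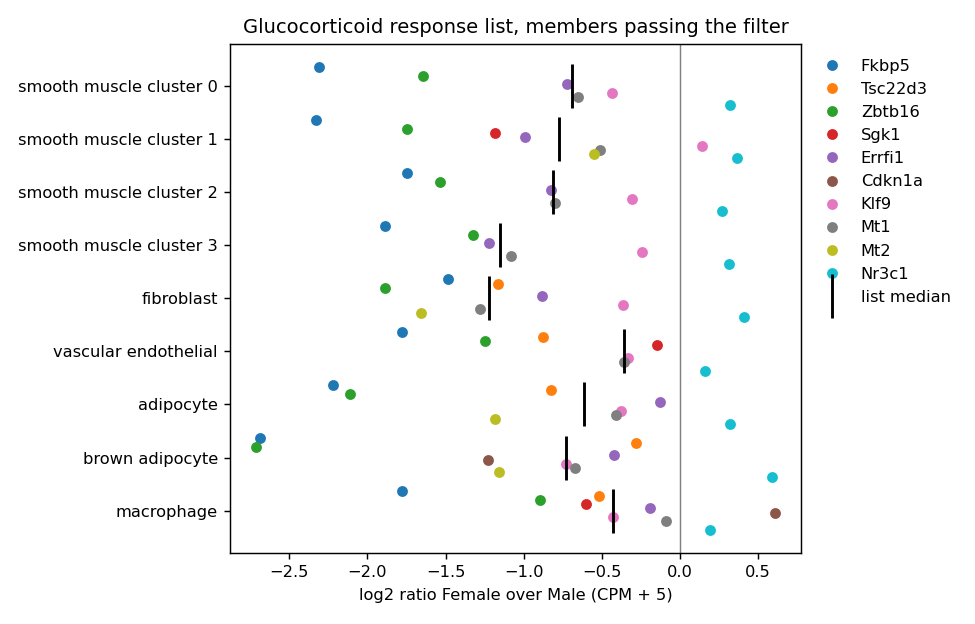
Log2 ratio of Female to Male CPM (pseudocount 5 CPM) in the 9 units, with 1 point per measured member of the glucocorticoid response list and a black bar at each list median. All 9 medians lay below 0, from -1.22 in fibroblasts to -0.36 in endothelial nuclei.

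The lineage reporter separated the cell classes much more than the sexes. GFP made up 91.6% of reporter UMIs in Female and 91.7% in Male smooth muscle cluster 3 (89.2 to 93.7 and 89.0 to 93.9), against 52.2% and 52.5% in cluster 0, 53.6% and 51.9% in cluster 2, and 66.2% and 61.1% in cluster 1. In fibroblasts it was 63.9% and 65.8%. The small fibroblast cluster 4 reached 80.8% (69.9 to 89.1) and 95.7% (88.0 to 99.1). Schwann or glial-like nuclei, a known neural crest derivative, had 24 GFP and 1 tdTomato UMI in the Female library and 15 and 1 in the Male library. Endothelial nuclei had the lowest large-class shares, 16.0% (15.1 to 17.0) and 14.99% (14.2 to 15.8). Mesothelial nuclei had 18.5% and 20.4% and macrophages 24.3% and 18.9%. The GFP share of the adipocyte classes differed between the libraries. It was 51.7% (47.9 to 55.5) Female and 38.6% (35.6 to 41.7) Male in white adipocytes. In brown adipocytes it was 52.3% (49.1 to 55.5) and 42.3% (38.6 to 46.1). GFP itself stood at 91.4 Female and 81.9 Male CPM in white and 72.99 and 70.9 CPM in brown adipocytes, with overlapping intervals. tdTomato was lower in the Female library, at 85.3 against 130.01 CPM in white and 66.6 against 96.6 CPM in brown adipocytes. Nuclei with GFP UMIs alone were less frequent there, at 17.7% against 22.1% in white and 19.5% against 23.2% in brown adipocytes. In endothelial nuclei, 9.95% of Female and 9.03% of Male nuclei carried UMIs of both reporters. With median depths of 3072 and 2970 UMIs there, against 3711 and 2846 in smooth muscle cluster 0, GFP stood at 57.0 and 54.4 CPM in endothelial nuclei and at 140.7 and 160.7 CPM in that cluster.

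**Figure D3:**
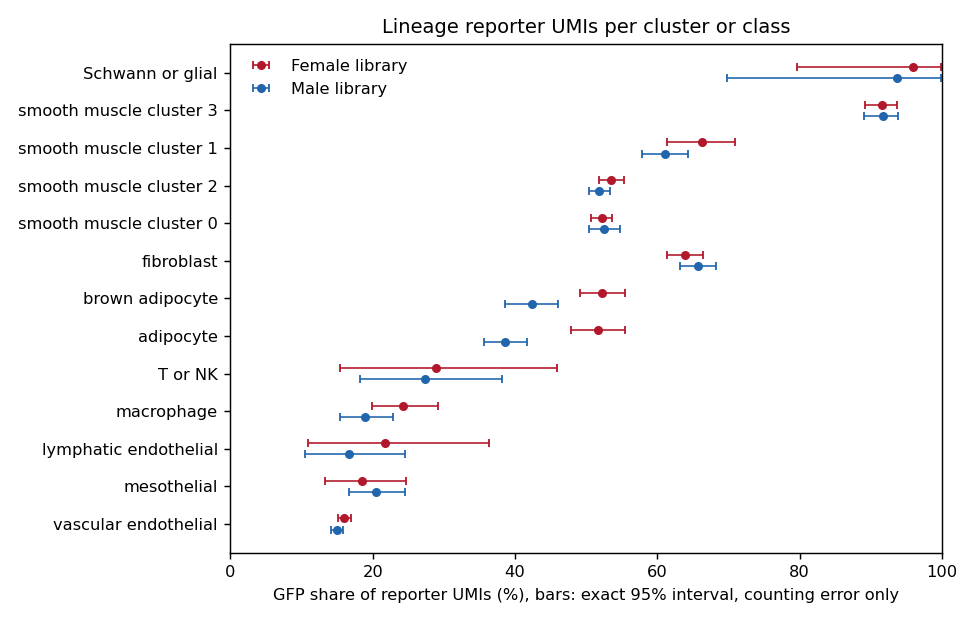
GFP as a percent of all reporter UMIs (GFP plus tdTomato) by class and library, with exact 95% intervals for counting error. Smooth muscle cluster 3 stood above 91% in both libraries and endothelial nuclei at 16.0% and 14.99%.

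Within smooth muscle clusters 0 and 2, nuclei carrying GFP UMIs alone were compared with nuclei carrying tdTomato UMIs alone, since the reporter marks descendants of Wnt1-Cre cells. This comparison and its clusters were chosen after the data were seen. As few as 1 reporter UMI placed a nucleus in its group. GFP-only nuclei made up 28.0% and 26.4% of Female and Male nuclei in cluster 0 and 33.3% and 33.1% in cluster 2. In classes that arise outside the neural crest, they made up 4.42% and 6.48% of T or NK-like nuclei (median 1558 and 1487 UMIs) and 7.21% and 6.14% of macrophage-like nuclei (median 2280 and 2500 UMIs), against medians of 3711 and 2846 UMIs in cluster 0 and 4639 and 4116 in cluster 2. Some nuclei of either group can therefore be of the other origin, and the groups are named by reporter, not by origin. GFP-only nuclei had more Nkain2, a partner of the sodium pump (cluster 0, log2 fold change 0.89 ± 0.06 SE; cluster 2, 1.13 ± 0.05), the synaptic scaffold gene Dlgap1 (0.93 and 0.62), the potassium channel gene Kcnt2 (0.81 and 0.68) and Tenm3 (0.70 and 0.74). They had less Sema3a, a secreted guidance cue (chromosome 5: 13125414 to 13602565; -2.50 ± 0.17 and -3.17 ± 0.18), Dgkg (-1.35 and -1.27), the HoxB genes Hoxb3 (-1.35 and -1.36) and Hoxb4 (-1.61 and -1.70), which mark position along the body axis, the matrix glycoprotein gene Tnc (-1.16 and -0.88), Ccdc3 (-0.78 and -0.65), Rgs7 (-0.53 and -0.48) and the receptor tyrosine kinase gene Erbb4 (-0.44 and -0.43). These were among 13 genes that passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment and DESeq2 in both clusters, 5 higher and 8 lower in GFP-only nuclei.

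For Sema3a the adjusted p was 4.86e-14 in cluster 0 and 4.18e-62 in cluster 2 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 2.70e-09 and 5.30e-18 by DESeq2. Sema3a moved the same way in both libraries and was at 99.0 and 49.8 CPM in Female and Male tdTomato-only nuclei of cluster 0 and at 16.8 and 10.6 CPM in GFP-only nuclei. Genes passing DESeq2 as well as edgeR in cluster 0 but not in cluster 2 included Pde1c (1.81 ± 0.11), a cyclic nucleotide phosphodiesterase, Dpp10 (1.62), Dlx6os1 (2.67; 124 against 17 UMIs) and Pdzrn4 (0.48) on the GFP side, and 5430431A17Rik (-2.26), Hoxb6 (-3.73), Rgs17 (-1.63), Art3 (-1.12) and Unc5c (-0.41) on the tdTomato side. In cluster 2 but not in cluster 0 they included Kcnip4 (0.75), Cdh6 (0.62), Mfap4 (0.62), Cacna1d (0.55) and Gt(ROSA)26Sor (1.49), a transcript of the locus that carries the reporter, on the GFP side, and Ank3 (-2.04), Dlg2 (-1.51), Maf (-1.44), Mamdc2 (-1.25) and Ntn4 (-0.74) on the other. Except for Dlx6os1 and Pdzrn4, these genes were also called by edgeR in the other cluster. Among them were Pde1c (1.37) and Hoxb6 (-4.54) in cluster 2. Hoxb6 was sparse in GFP-only nuclei, with 4 Female and 4 Male UMIs in cluster 0 and 0 and 4 in cluster 2. In tdTomato-only nuclei it had 82 and 19, and 49 and 24. No difference between the clusters was tested. Kcnip4 also leads smooth muscle cluster 3 and Dlx6os1 sub-cluster 2. GFP made up 91.6% and 91.7% of reporter UMIs in Female and Male nuclei of that cluster, and 92.4% and 91.3% in that sub-cluster. Whether nuclei like these lie within clusters 0 and 2 was not tested.

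By count, edgeR's test called 141 genes in cluster 0, 67 higher in GFP-only and 74 in tdTomato-only nuclei, and 239 in cluster 2, 117 and 122. DESeq2 called 23 and 28, all among edgeR's. Of edgeR's calls, 140 of 141 and 239 of 239 had the same direction in both libraries, which a fit blocked on library selects for. Across all genes tested, which are not independent replicates, the log2 ratios of the 2 libraries had Pearson's r of 0.163 and 0.189. The clusters shared 33 genes on the GFP side and 47 on the tdTomato side, where independent lists would share 0.634 and 0.746. That expectation takes every gene as equally likely to be called. Both clusters come from the same 2 libraries and merged at the lower resolution, so the lists are not independent and the sharing is no replication. The fits had 4 sums of nuclei from 2 libraries and 1 residual degree of freedom. Their p-values rest on how far the difference between the reporters varied between 2 pooled libraries, with dispersion shared across genes. They do not measure the spread between animals. Without the library as a block, edgeR called 20 and 8 genes. The tdTomato-only nuclei were the deeper ones, with medians of 4277.5 Female and 3402 Male UMIs against 3832 and 3244 in GFP-only nuclei of cluster 0, and 4995 and 4514.5 against 4791 and 4218 in cluster 2. With every nucleus thinned to 1000 UMIs, which also left fewer genes to test, edgeR called 74 genes in cluster 0, 59 of them among the 141, and 53 in cluster 2, 49 of them among the 239.

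By gene list, of 17 measured elastic fibre and fibrillar collagen genes of cluster 2, 3 were higher (Mfap4, Loxl1 at 0.27 and Eln at 0.17) and 1 lower (Col8a1 at -0.52) over all genes tested, and 6 and 1 when adjusted over the list alone. No list was tested as a whole, and the list median of 0.15 lay below that of ribosomal protein genes (0.19), none of which was called. Of 15 immediate early genes, Fos (1.27), Fosb (1.51) and Egr1 (0.83) were higher in GFP-only nuclei of cluster 2 over all genes tested, and 6 when adjusted over the list alone, with none lower. Contractile genes split: Tagln (0.16) was higher and Des (-0.88) and Actg2 (-0.36) lower in cluster 2, with 3 higher and 3 lower of 15 when adjusted over the list alone, while in cluster 0 none passed over all genes and 1 was lower over the list alone. Of 6 measured neural crest regulators in cluster 2, none passed over all genes, and 3 were higher and 1 lower when adjusted over the list alone. Hand2 was at 10.7 and 14.2 CPM in Female and Male GFP-only nuclei against 5.56 and 6.82 CPM in tdTomato-only nuclei, Msx1 had a log2 fold change of 0.98 and Ednra of -0.93. Tgfb3 (0.45) was among the TGF-beta genes higher in GFP-only nuclei of cluster 2, and Notch3 (0.44) was the only Notch gene. Of the list members named here, only Mfap4 also passed in DESeq2, with adjusted p = 0.0362 against 1.31e-10 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

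**Figure D4:**
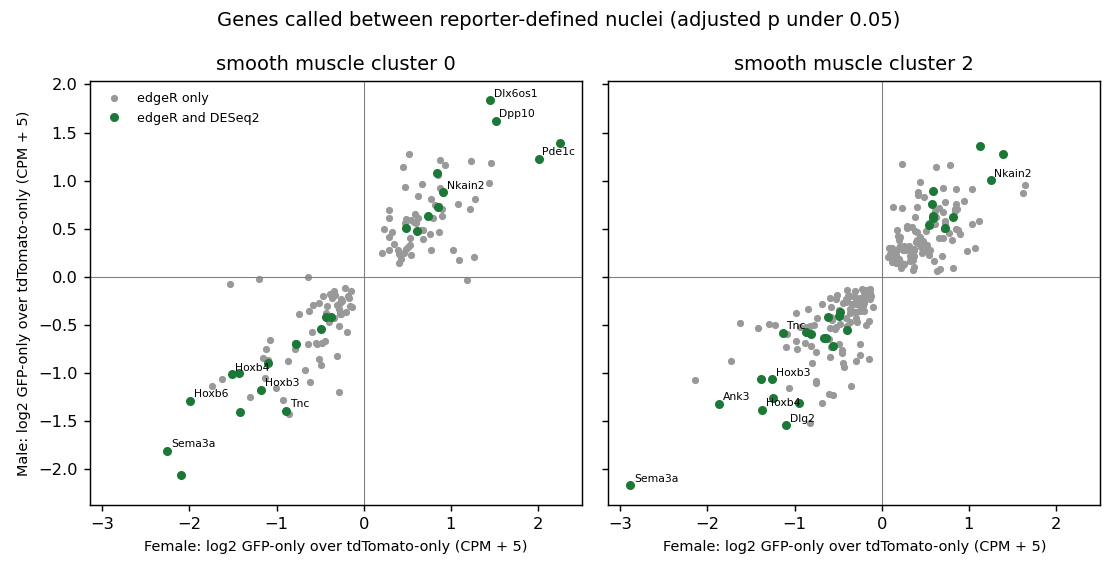
Log2 ratio of GFP-only to tdTomato-only CPM (pseudocount 5 CPM) in the Female library (x axis) and the Male library (y axis) for each gene called by edgeR alone (grey) or by edgeR and DESeq2 (green) in smooth muscle clusters 0 and 2, with some genes of the text labelled. Nkain2 lay above 0 and Sema3a, Hoxb3 and Hoxb4 below 0 on both axes in both clusters.

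In fibroblasts the same comparison gave few genes by both tools. In cluster 13, GFP-only nuclei had more Esrrg, an oestrogen-related receptor (log2 fold change 1.73 ± 0.15 SE), Stk32a (3.18 ± 0.29) and Pdzrn4 (3.26 ± 0.40). In cluster 9 they had more Epha3, an ephrin receptor (1.21 ± 0.15), and the phosphodiesterase gene Pde4d (1.03 ± 0.14), and less Nxph1 (-1.76 ± 0.21) and the glypican gene Gpc3 (-1.24 ± 0.15). For Esrrg the adjusted p was 8.38e-28 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment and 2.88e-08 by DESeq2. Of 4 measured thermogenic genes, Esrrg and Prdm16 were higher in GFP-only nuclei of both clusters by edgeR, over all genes and when adjusted over the list alone. By edgeR's test 135 genes were called in cluster 9 (57 GFP, 78 tdTomato) and 126 in cluster 13 (73 and 53), DESeq2 4 and 3. With the reporter shuffled between nuclei, up to 20 and 16 genes were called. With at least 2 reporter UMIs per nucleus edgeR called 0 genes in cluster 9 (282 at an unadjusted p under 0.05) and 43 in cluster 13, and without the library block 0 in cluster 9 (451 unadjusted) and 4 in cluster 13. Thinned nuclei gave 12 and 53 genes, and a minimum of 200 UMIs per gene gave 6 and 57.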

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

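No test was run on the differences in this part, and that some of them run opposite ways in different units was not tested. Alternatives for single genes were run only where the rule for named genes had taken the gene in that unit. The long non-coding Gm26870 was lower in the Female library in fibroblasts (log2 ratio -1.70) but higher in white adipocytes (1.07), brown adipocytes (1.42), macrophages (1.49) and smooth muscle clusters 0 (1.15), 1 (2.70) and 3 (2.96). Ntm, a cell adhesion gene, was higher in Female fibroblasts (1.29) and lower in smooth muscle cluster 3 (-1.94). Papss2, which makes the sulfate donor used for proteoglycans, was lower in Female fibroblasts (-1.06) and smooth muscle cluster 0 (-1.03) and higher in brown adipocytes (1.01). Prg4 was lower in Female fibroblasts (-1.52) and higher in macrophages (1.86). Gramd1b was lower in Female brown adipocytes (-1.28) and higher in smooth muscle cluster 3 (1.06).

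Heart muscle genes ran opposite ways in smooth muscle clusters 1 and 3: the log2 ratio was -3.32 and 3.80 for Ttn, -1.14 and 2.29 for Tnnt2 and -1.04 and 1.19 for Tnni3k. The Female side of cluster 3 held 454 UMIs of Myh6, a cardiac myosin heavy chain, in 5 of 822 nuclei. Those nuclei also held 143 of its 154 Tnnt2 UMIs. Over all retained nuclei, 25 Female and 13 Male nuclei held a Myh6 UMI. How the heart muscle UMIs of cluster 1 spread over its nuclei was not examined. Without nuclei with a Myh6 UMI, a setting chosen after seeing the data, cluster 3 had 46 genes at least 2-fold apart in place of 60.

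A cluster of 28 nuclei, 12 Female and 16 Male, was led by the airway epithelial genes Bpifa1, Scgb1a1 and Scgb3a1, in data from aorta and arch.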

How the results depend on the processing

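The alternatives that kept the largest cluster of each class alone or removed nuclei with a Myh6 UMI, all those of GFP shares and all those of the reporter comparison were chosen after seeing the data. No paired analysis was possible for the sexes because the groups share fewer than 2 replicate numbers and that comparison has no test. The reporter comparison was paired within library by its block; leaving out a library of the reporter comparison leaves no residual degrees of freedom, so it gave no value. Of the alternatives, 292 left a list median within its counting interval and 55 moved it; for GFP shares these numbers were 76 and 14, for counts of genes 2-fold apart 81 and 37, for genes called by reporter 12 and 16, and for single genes 987 and 681, with 4 reversed. For shares of nuclei they were 40 and 9, with 4 reversed, of which 3 are values of merged clusters. RLE scaling and a minimum of 10 UMIs were run on the reporter comparison alone and moved none of its 4 counts by over 1.5 times. Removing Myh6 nuclei was run on the count of genes apart in smooth muscle cluster 3 alone, which was 46 in place of 60. Except where stated, the cause was not tested. Some changes are missed: in simulated counts with counting error alone, 89% of 3-fold changes were recovered in macrophages, 93% in smooth muscle cluster 3 and 94% in cluster 1.

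At Leiden resolution 0.4, smooth muscle clusters 0 and 2 fall into 1 merged cluster by construction: its share difference was 8.005 points, which has the opposite sign to that of cluster 2 but is not of that cluster alone, and it had 22 genes 2-fold apart, a glucocorticoid median of -0.82 and a Notch median of 0.20; cluster 1 differed by -3.85 points. With doublets kept they also merge, with a difference of 12.89 points, again not of cluster 2 alone. Its GFP shares were 49.7% Female and 47.9% Male, and its medians were -0.65 for glucocorticoid, -0.083 for contractile, -0.077 for TGF-beta, -0.057 for heritable aortic disease and 0.18 for Notch genes. Cluster 1 then had 22 genes apart, the immediate early median of white adipocytes was 1.165, and GFP shares were 58.5% and 60.1% in fibroblasts and 25.1% in Male macrophages. With the libraries clustered separately, the share differences of smooth muscle clusters 0, 2 and 1 were 2.04, 3.05 (reversed) and -0.697 points, and 25, 34 and 42 genes were apart. In cluster 2 the contractile median was then -0.27 and the TGF-beta median -0.10, and GFP shares were 49.2% Female and 48.15% Male in cluster 0, 55.9% Female in cluster 2 and 56.3% Female in cluster 1. Without 2-fold genes in the clustering, cluster 1 had 16 genes apart, the immediate early median of white adipocytes was 1.25, that of heritable aortic disease in cluster 2 was 0.022, and cluster 0 had GFP shares of 48.4% and 47.4%. With the stricter nuclei filter, cluster 1 had 37 genes apart, the mitochondrially encoded median of macrophages was 0.39 and the Male GFP share of cluster 0 was 48.7%.

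Sub-clustering at resolution 0.2 merged sub-clusters 0 and 1, with a difference of -1.12 points, which is not of sub-cluster 1 alone. On thinned nuclei sub-clusters 0 and 3 merged, at -24.38 points, and sub-cluster 1 was at 23.62.

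With a pseudocount of 1 CPM, 19 genes were apart in smooth muscle cluster 0, 23 in cluster 2, 168 in cluster 1, 95 in cluster 3 and 145 in macrophages, and the immediate early median of white adipocytes was 1.765. With 20 CPM, which shrinks the ratios of low genes by construction, 8 were apart in endothelial nuclei, 5 in smooth muscle cluster 0, 5 in cluster 2, 15 in cluster 1, 25 in cluster 3, 24 in fibroblasts, 32 in brown adipocytes, 36 in macrophages and 108 in white adipocytes. The glucocorticoid medians were then -0.50 in smooth muscle cluster 0, -0.92 in fibroblasts and -0.62 in cluster 2, the immediate early medians 0.92 in white and 0.74 in brown adipocytes and -0.26 in fibroblasts, and the endothelial mitochondrially encoded median -0.33. With no CPM filter, more genes enter by construction: 298 were apart in smooth muscle cluster 1, 102 in cluster 3 and 191 in macrophages. Glucocorticoid medians were -0.63 in endothelial nuclei, -0.441 and -0.443 in smooth muscle clusters 0 and 2, -0.75 in cluster 3 and -0.38 in white adipocytes. Immediate early medians were 0.95 in white and 0.66 in brown adipocytes, the fibroblast clock median 0.47, the Notch median of cluster 2 0.090, its sex steroid median 0.086 and the endothelial mitochondrially encoded median -0.25. The stricter gene filter tests fewer genes by construction: 8 were apart in endothelial nuclei, 6 in smooth muscle cluster 0, 13 in cluster 1, 25 in cluster 3, 36 in fibroblasts, 49 in brown adipocytes and 29 in macrophages. The glucocorticoid median was then -0.88 in endothelial nuclei and -0.83 in white adipocytes, and the fibroblast clock median 0.42.

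Of the list medians and counts of genes apart, TMM scaling moved the contractile median of cluster 2, to -0.26, and no count by over 1.5 times, though white adipocytes had 172 Female-higher and 62 Male-higher genes in place of 150 and 79. With each nucleus weighing the same, cluster 1 had 143 genes apart, glucocorticoid medians were -0.63 in endothelial nuclei and -0.71 in cluster 2, the contractile median of cluster 2 was -0.18 and the macrophage mitochondrially encoded median 0.29. With nuclei thinned to 1000 UMIs, 24 genes were apart in smooth muscle cluster 0, 26 in cluster 2 and 48 in macrophages. Glucocorticoid medians were -0.62 in endothelial nuclei, -1.08 in fibroblasts, -0.64 in smooth muscle cluster 2, -0.98 in brown adipocytes, -1.345 in cluster 3 and -0.87 in white adipocytes. In cluster 2 the contractile median was -0.14, that of heritable aortic disease -0.048 and that of sex steroid genes 0.44, and the macrophage mitochondrially encoded median was 0.39. In the largest cluster of each class alone, 13 genes were apart in endothelial nuclei, the glucocorticoid median of fibroblasts was -0.93 and their immediate early median -0.21. The endothelial function median was -0.11, and the mitochondrially encoded medians were -0.31 in endothelial nuclei and 0.32 in macrophages. Log2 ratios reversed there for Cxcl13 (-1.13), Rp1 (-0.40) and Tgfb2 (-1.76) in macrophages and Nckap5 (0.34) in endothelial nuclei.

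For genes called between GFP-only and tdTomato-only nuclei, DESeq2 gave 23 in smooth muscle cluster 0, 28 in cluster 2, 4 in fibroblast cluster 9 and 3 in cluster 13. Without the library block edgeR gave 20, 8, 0 (451 at an unadjusted p under 0.05) and 4. Thinned nuclei gave 74, 53, 12 and 53. At least 2 reporter UMIs gave 0 (282 unadjusted; DESeq2 on all nuclei gave 4) in fibroblast cluster 9 and 43 in cluster 13, from fewer nuclei, and a minimum of 200 UMIs gave 6 and 57, from fewer genes.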

Other observations

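All tests in this part were chosen after the result was seen, except the shuffling of the reporter over the 4 clusters together. Several smaller populations were seen. Macrophage clusters 18 and 15 made up the compared macrophage unit, and endothelial cluster 20 was part of the endothelial unit. T or NK-like nuclei were not part of the comparisons. Macrophage cluster 18, led by F13a1, Mrc1 and Cd163, held 2.45% of Female and 3.42% of Male nuclei, while macrophage cluster 15, led by Lyz2, Mmp12 and Cybb, held 0.648% and 0.592%. Endothelial cluster 20, led by Gpihbp1, Cd300lg and Car4, genes of capillary endothelium, had 46 Female and 32 Male nuclei. Among smooth muscle sub-clusters, GFP made up 65.6% of Female and 60.7% of Male reporter UMIs in sub-cluster 0 and 49.9% and 48.8% in sub-cluster 1. In sub-cluster 3, led by Fth1, Hspb1 and Clu, 40 of the Female reporter UMIs were GFP and 1 was tdTomato. T or NK-like nuclei, which arise outside the neural crest, had GFP shares of 28.9% and 27.4%. Over all retained nuclei, 48.9% of the Female and 49.96% of the Male nuclei carried neither reporter.

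Of the 81 Xist UMIs in the Male library, 23.5% (14.8 to 34.2) lay at barcodes also found in the Female library, and 20.8% of Male barcodes were such barcodes.

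Glucocorticoid response genes were lower in the Female library in all 9 units. Free RNA from a single cell type would add about the same number of Fkbp5 UMIs to every nucleus. The Male excess per nucleus was 16.5 times as high in white adipocytes as in smooth muscle cluster 1. It was 2.82 in white adipocytes, 1.71 in macrophages, 1.54 in fibroblasts and 1.25 in brown adipocytes. These values argue against free RNA of 1 cell type as the whole cause in those units. The excess was 0.35 in endothelial nuclei and 0.46, 0.38 and 0.52 in smooth muscle clusters 0, 2 and 3, and 0.17 in the shallow cluster 1. Free RNA stays open in these. Under TMM scaling and under equal depth per nucleus the list median stayed at percentile 0.01 or lower in 8 units. TMM scaling shifts all genes of a unit nearly alike, list and random lists together. Its percentile could therefore hardly change and decides nothing on scaling. The percentile at equal depth argues against depth in those 8 units. Equal depth left out the 248 of 615 Female and 689 of 1488 Male nuclei of smooth muscle cluster 1 that had under 1000 UMIs, and 6 of its 8 members stayed. In macrophages the list median reached percentile 3.02 at equal depth. There the median over the 5 members still measured was -0.25 (-0.81 to -0.03) against -0.52 (-0.79 to -0.36) for them at full depth, intervals that overlap and decide nothing. The criterion was applied unit by unit only after macrophages had missed it. A different clock phase at harvest may contribute: the activator arm of the clock lay below the output arm by the set amount in only 3 of 9 units, fibroblasts among them, while in endothelial nuclei (0.36) and smooth muscle clusters 3 (0.31) and 0 (0.29) it lay above by more than counting error, which goes against a shift shared by all units but rests on 1 or 2 activator genes, so this stays open. Sex, handling or stress of the animals before tissue collection stays open as untested.

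GFP UMIs in endothelial nuclei, which mostly carried tdTomato, were found together with tdTomato UMIs more often than depth gives. The odds ratio given depth was 1.66 (1.39 to 1.98) in the Female and 1.49 (1.28 to 1.75) in the Male library, against 1.06 and 1.05 for GFP with Myh11. Myh11, a smooth muscle transcript, was taken to reach endothelial nuclei as free RNA, which was not measured. If it does, these odds argue against free RNA as the whole source of the GFP UMIs. Transcripts of the reporter locus that carry both reporters may be a source, since they need odds above 1 in endothelial nuclei of both libraries. In smooth muscle clusters 0 and 2 the odds were below 1, from 0.290 to 0.372. Those clusters mix GFP-only and tdTomato-only nuclei, which lowers the odds with or without such transcripts, so these odds decide nothing on them. No biological explanation was tested.

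UMIs clumped in few nuclei may inflate the number of genes called between GFP-only and tdTomato-only nuclei. With the reporter shuffled between nuclei of the same library and cluster in 20 draws, the highest count was 14.8% of the real count over the 4 clusters, in fibroblast cluster 9, which was above the limit set beforehand and leaves this open for the fibroblasts. In the smooth muscle clusters it was at most 6.38%, with up to 9 calls against 141 in cluster 0 and up to 5 against 239 in cluster 2, which argues against clumping as the whole cause there. Embryonic origin remains a hypothesis for those genes, since nuclei were grouped by as few as 1 reporter UMI and the position of the nuclei along the aorta, which can differ with origin, was not measured.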
